A study of Rattus norvegicus with 6 samples.

How the data were processed

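Total RNA from the right ventricle of 3 MCT-treated and 3 saline-treated rats was analysed. Per the labels' protocols, RNA was pretreated to remove modifications that block library making, ligated to 3′ and 5′ adapters, reverse transcribed, amplified and size-selected on a gel. The labels' protocols also describe hybridization to a small RNA microarray. The file used here holds sequencing values and no array intensities, so the assumption of array values made before the data were examined was replaced by the test set out beforehand for CPM. Per the submitters' processing notes, Bowtie was used and the build mm10 is named, with no version and no role. That is a mouse build, whereas the samples are from rat, and how it entered the values is not given in the sources used here. The counting rule for reads that match several tRNAs, and any filter on low fragments, are not given in the sources used here.

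The authors deposited 1 table for the series, with a line per fragment giving its sequence, class, length in nt and the parent tRNA sequences it aligns to. Per the file headers, the values of each library are CPM, counts of reads scaled by the authors to a common library total. The CPM columns named PH were taken as MCT and those named N as control, by group and number in the sample titles. The authors' log2 fold changes and log2 group means, their fold ratio and their p-values and q-values were copied from the deposited table and used only where they are named as the authors'. The deposited log2 fold change equals the difference of the deposited log2 group means. A further 224 lines of the table were not used here. Every CPM value used was a whole multiple of the smallest value in its column, to a tolerance of 0.001, so whole reads were recovered for 100% of values. The reads in the rows used make up 84.8% to 89.0% of the total behind the CPM values of each library, and those totals ranged from 221455 to 629056 reads. Each fragment used reached 20.4 CPM or more in at least 1 library. A fragment with no read in a library may stand at up to 3 reads, which is 4.77 CPM in control 1 and 13.5 CPM in control 2, and such limits cover counting error only.

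Positions are counted from 1 at the 5′ end of the parent tRNA, as the deposited fragment names give them. For precursor fragments they are counted in the precursor. No genome of these samples was used here, so no chromosome coordinates are given. Parent tRNAs were named by the first parent in the fragment's name, and 714 fragments with several parents are uncertain as to their gene. A total of 2539 fragments had a read in all 6 libraries, 27 were at 0 in all MCT libraries and 2 in all control libraries.

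The main test was limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, on log2(CPM + 1) of all 3618 fragments with the group as the only term. Benjamini-Hochberg adjustment was used, with an adjusted p of 0.05 as threshold. Fold changes are differences of mean log2(CPM + 1), which for low fragments, and above all those at 0 in some libraries, can be smaller or larger than the log2 ratio of mean CPM. Fragment classes, as the deposited table names them, and lists fixed before the data were examined were tested with camera at a preset correlation of 0.01. Of 35 preset lists, 17 of microRNAs and 3 of small nucleolar RNAs matched no fragment, and 14 of 15 tRNA fragment lists matched at least 3. The list of internal tRNA fragments matched none, since no row used has a class of that name. The mitochondrial list was matched on the table's chromosome name for mitochondrial tRNAs. Shares of reads were compared by two-sided exact permutation tests in scipy 1.17.1, and shares of single libraries have exact 95% Clopper-Pearson intervals. Labels state separate rat tissue samples without further detail on the animals, so p-values measure the spread between these samples. No pair of libraries agreed within sampling noise by a chi-square test of their reads.

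Named fragments were chosen by a rule fixed before the data were examined. It took fragments past the threshold, and, where fewer than 3 per direction passed, those with the lowest unadjusted p up to 3, said not to have passed. It also took up to 3 fragments with the lowest p in each matched list. The heart, fibrosis and blood microRNAs that the rule also names were not measured. Fragments outside the rule are said to be chosen after their values were seen. Not every fragment taken by the rule is given a value in the text.

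Alternatives set beforehand were a replicate block, quantile normalization, median centring, a filter on the lowest 25% of fragments, pseudocounts of 0.1 and 5, leaving out each library, limma without trend or with robust fitting, other thresholds, an estimated correlation, and fry. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood test with TMM) and DESeq2 1.42.0 on the recovered reads, CPM rescaled within mitochondrial and nuclear fragments, the log2 ratio of mitochondrial to nuclear reads as a covariate, sums per parent tRNA, and shares of reads. DESeq2 gave an adjusted p for 3602 fragments. Tests were first run on simulated reads for 3618 fragments, drawn from the means and spread of these libraries. There were 20 simulations with 200 changed fragments outside the 100 most abundant. Each fragment was drawn independently, so variation that fragments share within a library was not simulated. For MCT against control so simulated, limma recovered 7.69% of 4-fold, 64.9% of 16-fold and 95.3% of 64-fold changes, with 3.2 false calls on average. The edgeR test recovered 9.7%, 75.9% and 99.2%, with 4.15 false calls. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.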

Results

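Small RNA was sequenced from right ventricular tissue of rats given monocrotaline (MCT), a plant alkaloid that injures lung vessels and is widely used to induce pulmonary arterial hypertension, and of control rats given saline. Both groups had 3 libraries, taken at 4 weeks. The part of the deposited table used here lists 3618 RNA fragments derived from transfer RNAs (tRNAs), 14 to 40 nt long, of which 2327 came from mitochondrial (mt) tRNAs and 1291 from nuclear tRNAs. A total of 584 fragments lay in precursor tRNAs, and 714 were assigned to several parent tRNA genes of near-identical sequence, so that their gene of origin was uncertain. The CPM values were whole multiples of what 1 read was worth, and the reads recovered from them numbered 312739, 258452 and 507542 in MCT replicates 1 to 3 and 538909, 193423 and 290322 in control replicates 1 to 3. A single read stood for between 1.59 CPM in control 1 and 4.52 CPM in control 2. The question was whether tRNA fragments of the right ventricle differed between MCT-treated and control rats.

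In the right ventricle, fragments of nuclear tRNA-Gly took from 20.9% to 74.0% of the reads of a library and those of mt-His-GTG from 6.05% to 29.6%. Fragments of mt-Ser-GCT took 27.7%, 25.2% and 18.5% in MCT 1, MCT 3 and control 1, and 2.34%, 3.75% and 2.78% in MCT 2, control 2 and control 3. On the mean over the 6 libraries the most abundant fragment was the first 31 bases shared by tRNA-Gly-CCC and tRNA-Gly-GCC (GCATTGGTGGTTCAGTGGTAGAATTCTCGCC), at 169880 ± 136051 CPM in MCT and 165123 ± 92201 CPM in control (mean ± SD, n = 3 each). The first 19 bases of mt-Ser-GCT (AAGAAAGTATGCAAGAACT) stood at 105628 ± 81635 CPM in MCT and 42239 ± 48385 CPM in control (SD, n = 3), with a log2 fold change of 1.26 ± 1.51 (SE). The fragment of mt-His-GTG from position 26 to 65 stood at 31442 ± 39168 CPM in MCT and 36789 ± 34926 CPM in control (SD, n = 3). The mt-Ser-GCT fragment was the more abundant of the first 2 in 3 libraries, MCT 1 (158875 against 120506 CPM), MCT 3 (146368 against 65411 CPM) and control 1 (98058 against 62487 CPM). In MCT 2, control 2 and control 3 it stood at 11641, 16396 and 12264 CPM against 323724, 191935 and 240946 CPM. These 3 fragments were chosen for their abundance after their values were seen. For none of them was the difference between groups larger than the spread between replicates.

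**Figure D1:**
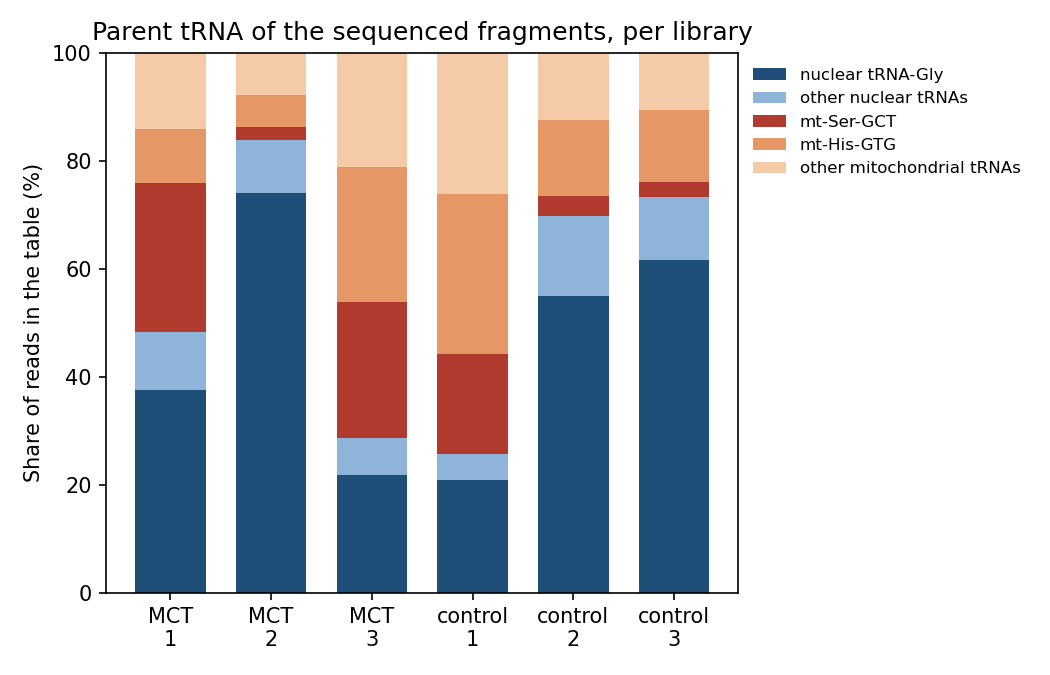
Stacked bars give, for each of the 6 libraries, the percent of reads in the rows used from nuclear tRNA-Gly, other nuclear tRNAs, mt-Ser-GCT, mt-His-GTG and other mitochondrial tRNAs. Nuclear tRNA-Gly took from 20.9% of reads in control 1 to 74.0% in MCT 2.

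The balance of mitochondrial and nuclear fragments differed widely between libraries of the same group. Mitochondrial fragments made up 51.8% (exact 95% Clopper-Pearson interval 51.6 to 51.9), 16.138% (15.996 to 16.28) and 71.3% (71.2 to 71.4) of reads in MCT 1 to 3. In control 1 to 3 they made up 74.2% (74.1 to 74.4), 30.163% (29.958 to 30.368) and 26.7% (26.6 to 26.9). These intervals cover counting error only. The group means were 46.4% ± 27.97 in MCT and 43.7% ± 26.5 in control (SD, n = 3; two-sided exact permutation p = 1). Nuclear tRNA-Gly fragments averaged 44.4% ± 26.8 and 45.9% ± 21.8 (SD, n = 3; exact permutation p = 1). The share of the 5′ class tRF-5c, of 28 to 32 nt, was 38.2% ± 28.1 in MCT and 39.8% ± 21.9 in control (SD, n = 3; exact permutation p = 0.9). The mt-Ser-GCT share was 18.4% ± 13.97 against 8.34% ± 8.79, and the mt-His-GTG share 13.7% ± 10.0 against 18.99% ± 9.23 (SD, n = 3; exact permutation p = 0.4 and 0.5). None of 23 such shares differed after Benjamini-Hochberg adjustment (adjusted p = 1 in each exact permutation test), in a design whose smallest two-sided p is 0.1. The sign of the mitochondrial, tRNA-Gly and tRF-5c differences changed when single libraries were left out, so none of the 3 has a stable direction. The other shares, those of mt-Ser-GCT and mt-His-GTG among them, were not compared with libraries left out.

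**Figure D2:**
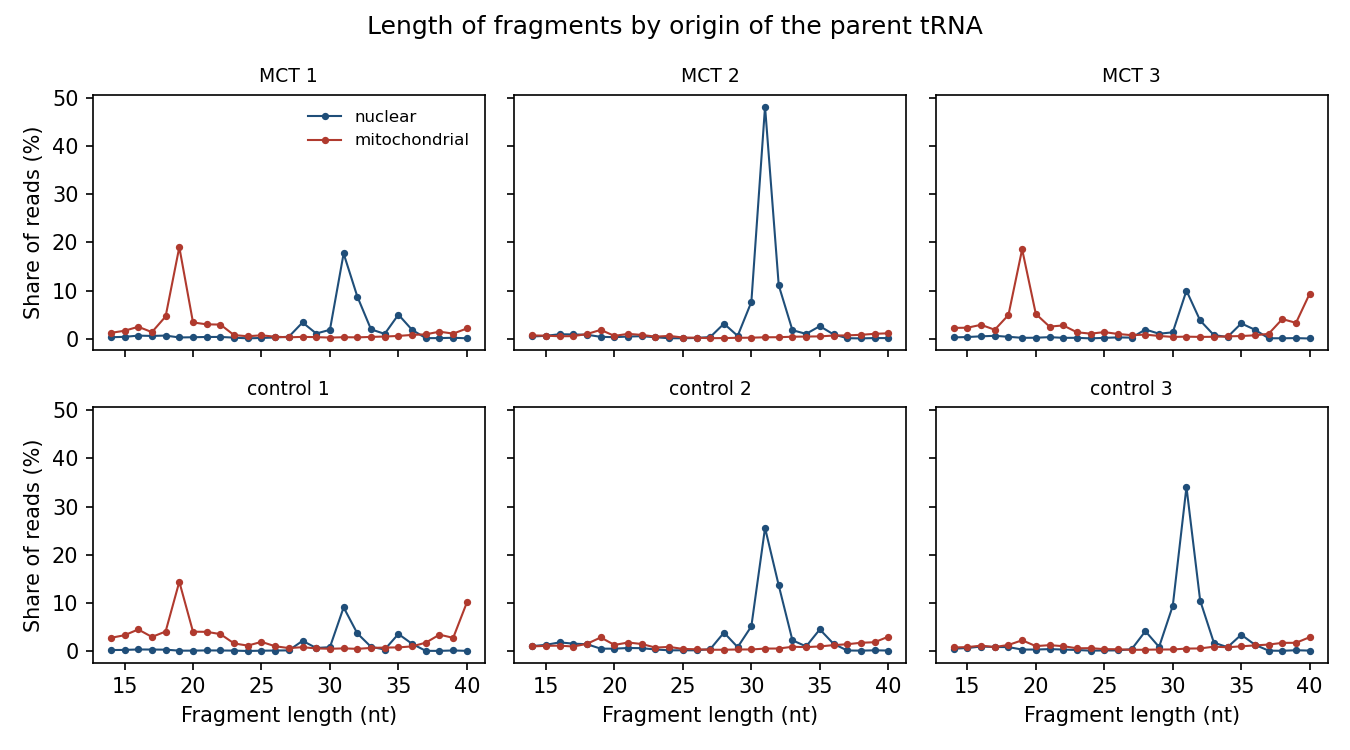
Each panel plots, for 1 library, the percent of reads (y axis) at each fragment length in nt (x axis), split into nuclear and mitochondrial parent tRNAs. The nuclear peak at 31 nt holds 48.1% of reads in MCT 2 and 9.08% in control 1, and the mitochondrial peak at 19 nt holds 19.005% in MCT 1 and 1.84% in MCT 2.

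In a principal component analysis of log2(CPM + 1), component 1 (49.3% of variance) placed MCT 1, MCT 3 and control 1 on one side and MCT 2, control 2 and control 3 on the other. Component 2 (17.5% of variance) ran from -54.2, -22.0 and -9.02 in the MCT libraries to 18.3, 50.2 and 16.7 in the control libraries, without overlap. Chance sets groups of 3 and 3 apart on any given component in 10% of cases, so this alone does not mark component 2 as an axis of treatment.

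**Figure D3:**
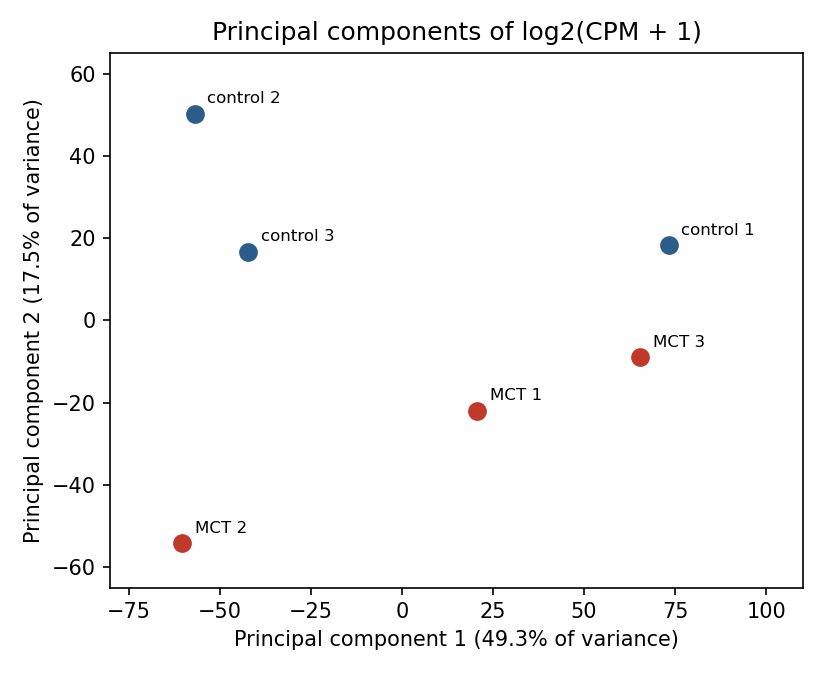
Points are the 6 libraries on principal components 1 (x axis, 49.3% of variance) and 2 (y axis, 17.5%) of log2(CPM + 1), in arbitrary units. MCT 3 (65.5) and control 1 (73.3) lie at one end of component 1, and MCT 2 (-60.2) and control 2 (-56.9) at the other.

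The fragments that stood furthest apart between the groups by their unadjusted p were 2 of tRNA-Gly-CCC-2 and 1 of tRNA-Gln-CTG on the higher side and 3 of mt-Leu-TAA on the lower side, and none passed the adjusted threshold. The 35 nt 5′ fragment of tRNA-Gly-CCC-2, which ends at the last base of the CCC anticodon (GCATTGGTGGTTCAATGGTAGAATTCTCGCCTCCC), stood at 263 ± 22.2 CPM in MCT and 41.7 ± 11.2 CPM in control (SD, n = 3). Its values were 238, 278 and 274 CPM in MCT 1 to 3 against 50.9, 45.2 and 29.2 CPM in control 1 to 3, a log2 fold change of 2.66 ± 0.72 (SE). The 34 nt form (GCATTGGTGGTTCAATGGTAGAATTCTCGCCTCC) stood at 152 ± 91.6 against 28.1 ± 16.3 CPM (SD, n = 3), with all 3 MCT libraries above all 3 control libraries. An internal fragment of tRNA-Gln-CTG from position 13 to 41 (TAATGGTTAGCACTCTGGACTCTGAATCC) stood at 84.2 ± 57.4 against 9.55 ± 8.87 CPM (SD, n = 3). On the lower side, 3 nested fragments of mt-Leu-TAA began at position 30, in the anticodon arm. The one ending at position 60 (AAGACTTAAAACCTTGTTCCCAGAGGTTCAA) stood at 5.12 ± 4.51 CPM in MCT and 71.4 ± 30.9 CPM in control (SD, n = 3), with a log2 fold change of -4.00 ± 1.07 (SE). In MCT 3 it had no read, which allows up to 5.26 CPM. The forms ending at positions 63 and 58 had log2 fold changes of -4.00 ± 1.13 and -3.28 ± 1.02 (SE), with no overlap between the groups. They stood at 2.83, 3.44 and 0 CPM and at 11.3, 6.87 and 1.75 CPM in MCT 1 to 3, where 1 read was worth 2.83, 3.44 and 1.75 CPM. Values so near the floor make the size of the fold change depend on the pseudocount. For the form ending at position 63 it was -5.31 with 0.1 and -2.71 with 5.

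**Figure D4:**
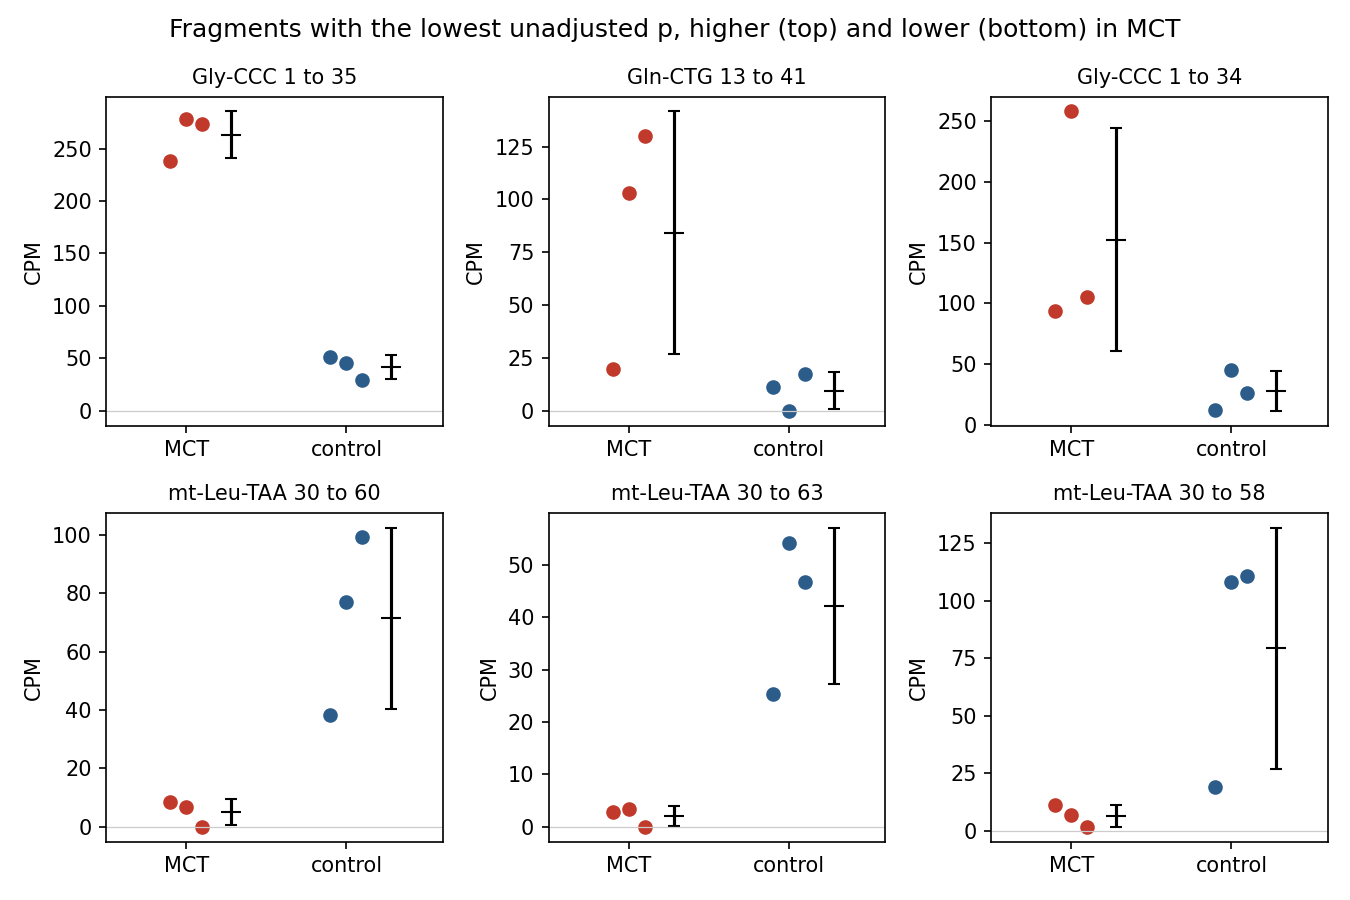
Points are CPM values (linear y axis, a separate scale in each panel) of the 3 MCT and 3 control libraries for the 3 fragments with the lowest unadjusted p in each direction, with mean ± SD as bars beside them. The MCT points of Gly-CCC 1 to 35 lie between 238 and 278 CPM, above the control points at 29.2 to 50.9 CPM, and the panels of mt-Leu-TAA show the MCT points below the control points; none of the 6 passed the adjusted test.

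Across all 3618 fragments, 0 passed an adjusted p of 0.05 with limma (lowest adjusted p = 0.995). At an unadjusted p under 0.05, limma counted 86 fragments, 21 higher and 65 lower in MCT, all with a fold of at least 1.5, where chance would give 180.9. Of the 21 higher fragments, 9 came from Gly-CCC and 6 from mt-Cys-GCA. Of the 65 lower fragments, 60 were mitochondrial, among them 13 from mt-His-GTG, 9 from mt-Pro-TGG, 8 from mt-Lys-TTT and 7 from mt-Leu-TAA. Among all 3618 fragments, 2327 were mitochondrial, 421 came from mt-His-GTG and 126 from Gly-CCC. Nested forms of the same piece, such as those of mt-Leu-TAA, were counted separately. The edgeR quasi-likelihood test and DESeq2 on the recovered reads also called 0 fragments, with 83 and 77 at an unadjusted p under 0.05 and a fold of at least 1.5. For the 35 nt fragment of tRNA-Gly-CCC-2 the DESeq2 adjusted p was 0.11 and the edgeR adjusted p 0.996. The MCT and control values did not overlap for 348 fragments, 9.62% of those used, where chance gives 10%. The median log2 fold change of all fragments was -0.38 as deposited, and it was -0.01 after quantile normalization and 0.02 after centring each library on its median. With those scalings the 21 higher and 65 lower fragments became 50 and 28, and 65 and 18, so the excess on the lower side depended on the scaling. The count of 86 became 217 without MCT 2, 303 without control 1 and 33 without control 3. Over the libraries left out, the higher fragments from Gly-CCC numbered from 4 to 9 and the lower ones from mt-Leu-TAA from 3 to 13. In simulated data with the spread of these libraries, limma recovered 7.69% of 4-fold changes and 64.9% of 16-fold changes. Fragments were drawn there independently of each other, whereas those of the real libraries vary together, so these rates may not hold for the real libraries.

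The rule for named fragments took further fragments of these tRNAs, given here as values since none passed. The 36 nt 5′ fragment of tRNA-Gly-CCC-2 stood at 75.03 ± 37.3 CPM in MCT and 12.8 ± 6.65 CPM in control, and the 33 nt form, of the tiRNA-5 class, at 85.1 ± 78.1 and 18.2 ± 15.9 CPM (SD, n = 3). The 3 precursor fragments of mt-Lys-TTT so taken began at position 5. The one ending at position 40 stood at 63.3 ± 37.7 CPM in MCT against 287 ± 80.03 CPM in control (SD, n = 3), a log2 fold change of -2.30 ± 0.74 (SE). Fragments of mt-His-GTG from position 10 to 39 and from 16 to 47 stood at 11.1 ± 5.02 against 83.5 ± 56.9 CPM and at 76.8 ± 11.9 against 321 ± 138 CPM (SD, n = 3). Among fragments of tRNA-Glu, the lowest p belonged to the 3′ tRF-3b piece of mt-Glu-TTC from position 54 to 72, which ends in the CCA tail, at 2.09 ± 1.83 against 27.3 ± 23.4 CPM. For tRNA-Val, the fragment of mt-Val-TAC from position 45 to 71 stood at 3.23 ± 3.45 against 23.9 ± 8.61 CPM, while those from 19 to 32 and from 37 to 61 lay the other way, at 22.6 ± 5.45 against 9.54 ± 16.5 CPM and at 17.9 ± 8.38 against 4.24 ± 7.34 CPM, with overlap and with control 2 and control 3 at 0. For tRNA-Arg, the fragment of mt-Arg-TCG from position 19 to 36 stood at 0.585 ± 1.01 against 15.3 ± 6.64 CPM. For tRNA-Asp, the 3′ tRF-3a piece of mt-Asp-GTC from position 54 to 71 stood at 6.88 ± 1.61 against 27.4 ± 5.49 CPM, and the precursor fragment from 110 to 146 lay the other way, at 57.8 ± 5.60 against 24.4 ± 23.1 CPM (SD, n = 3 for each).

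Fragments of tRNA-Ser included the first 35 bases of mt-Ser-GCT, at 136 ± 76.2 CPM in MCT and 406 ± 233 CPM in control (SD, n = 3), a log2 fold change of -1.52 ± 0.77 (SE) against 1.26 for the abundant 19 nt form. Among 5′ fragments, the 22 nt tRF-5b piece of mt-Pro-TGG stood at 19.1 ± 3.06 against 69.5 ± 33.3 CPM. A 16 nt 5′ piece of the selenocysteine tRNA was listed at 0 in all 3 MCT libraries and at 13.9 ± 10.95 CPM in control. The tRNA-Ala list was led by the 3′ tRF-3a piece of Ala-AGC-1 from position 58 to 75, at 22.5 ± 12.2 against 81.2 ± 50.0 CPM, while the same piece of Ala-AGC-2 lay the other way, at 15.8 ± 13.4 against 3.18 ± 5.51 CPM (SD, n = 3), both with overlap between the groups. Trailers, the 3′ overhangs cut from precursor tRNAs by RNase Z, included a 15 nt piece of the initiator tRNA iMet-CAT. This trailer stood at 487 ± 275 CPM in MCT and 1281 ± 579 CPM in control (SD, n = 3), also with overlap.

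Of the lists fixed beforehand, fragments of tRNA-Gly, tRNA-Ser, tRNA-Arg and tRNA-Asp lay higher in MCT relative to the other fragments, and those of tRNA-Glu, tRNA-His, tRNA-Leu and the mitochondrial tRNAs lay lower, by limma's camera test with a preset correlation of 0.01. All 8 calls were lost when camera estimated the correlation from the data (adjusted p = 0.781 with an estimated correlation for each), and fry, which tests each list by itself, called 0 of 14 (lowest adjusted p = 0.126, tRNA-Leu). The lists of single tRNAs were matched by name and hold nuclear and mitochondrial fragments together, so they overlap with the mitochondrial list. Fragments of mt-Arg-TCG were 282 of the 358 for tRNA-Arg, those of mt-His-GTG 421 of the 537 for tRNA-His, and those of mt-Gly-TCC 82 of the 303 for tRNA-Gly. Those of mt-Ser-GCT were 86 of the 124 for tRNA-Ser, whose call was lost without MCT 1, MCT 3, control 2 or control 3. The 303 tRNA-Gly fragments had a median log2 fold change of -0.06 (mean -0.05; 145 above and 158 below 0; camera adjusted p = 0.0101), so they stood above the median of -0.38 of all fragments used and not above 0. The 358 tRNA-Arg fragments likewise had a median of -0.11 and a mean of -0.05 (camera adjusted p = 0.0165). The 124 tRNA-Ser fragments had a median of 0.11 and a mean of 0.08 (camera adjusted p = 0.0144), and the 98 tRNA-Asp fragments a median of 0.05 and a mean of -0.07 (camera adjusted p = 0.0496). On the lower side, medians were -0.67 for 138 tRNA-Glu fragments, -0.65 for 268 tRNA-Leu fragments, -0.53 for 537 tRNA-His fragments and -0.45 for 2327 mitochondrial fragments (camera adjusted p = 0.0496 for each). Of these lower lists, 110, 202, 400 and 1585 members had a log2 fold change below 0. After quantile normalization 4 lists were called, those of tRNA-Gly, tRNA-Ser, tRNA-Arg and tRNA-Asp, while leaving out MCT 1, control 2 or control 3 gave 3, 4 and 5 lists, of which 3 each were among the 8 with the same direction. The mitochondrial list turned to higher in MCT without MCT 2 (camera adjusted p = 0.0101) and without control 1 (camera adjusted p = 6.58e-07), the libraries at the ends of the range of mitochondrial share.

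The other 6 lists did not pass camera. The 181 5′ fragments had a median of -0.33 (adjusted p = 0.54), the 154 3′ fragments -0.56 (adjusted p = 0.0805), and the 35 trailers -0.54 (adjusted p = 0.79). With single libraries left out, the 5′ list was called higher without MCT 3 (camera adjusted p = 0.00267) and without control 3 (camera adjusted p = 0.004002), and lower without control 1 (camera adjusted p = 0.0432). The trailers were called lower without MCT 2 (camera adjusted p = 0.00403) and higher without MCT 3 (camera adjusted p = 0.0103), and 3′ fragments lower without MCT 2 and without control 1 (camera adjusted p = 0.000783 and 0.00836). Fragments of tRNA-Lys, tRNA-Val and tRNA-Ala had medians of -0.17, -0.31 and -0.23, with camera adjusted p of 0.199, 0.465 and 0.465. The tRNA-Lys list was called higher without MCT 3 (camera adjusted p = 0.00119) and without control 3 (camera adjusted p = 0.0312), and the tRNA-Ala list higher without MCT 3 (camera adjusted p = 0.010004) and without control 2 (camera adjusted p = 0.00211). Without the lowest 25% of fragments, the tRNA-Lys list was called higher and the 3′ list lower (camera adjusted p = 0.0178 and 0.0306). In each of the 14 lists, 0 fragments passed limma's test over all fragments and 0 adjusted over the list alone, where the lowest adjusted p was 0.288 for tRNA-Leu. The correlation between members estimated by camera ran from 0.00728 for tRNA-Leu to 0.525 for trailers.

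No class of fragment differed between the groups by camera. The class closest to the threshold was tiRNA-5, the 5′ pieces made by cleavage in the anticodon loop, whose 21 fragments had a median log2 fold change of 0.18 (13 above and 8 below 0; camera adjusted p = 0.15). The 79 tRF-3a and 71 tRF-3b fragments, which end in the CCA tail, had medians of -0.55 and -0.56, with 68 and 57 of them below 0 (camera adjusted p = 0.468 and 0.392). The 98 tRF-5c fragments had a median of -0.33 and the 35 tRF-1 trailers one of -0.54 (camera adjusted p = 0.673 and 0.79). The count of 0 classes of 10 became 5 without MCT 2, 4 without MCT 3 or without control 1, 2 without control 3 and 1 without control 2. With an estimated correlation camera also called 0 classes (lowest adjusted p = 0.947).

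Summed over all fragments of a parent tRNA, the levels of 66 tRNAs were also compared, a result added after the data were seen. Gly-CCC fragments, including those shared with Gly-GCC, totalled 277876 ± 189962 CPM in MCT and 303080 ± 165006 CPM in control, and mt-Ser-GCT fragments 163472 ± 123991 and 71539 ± 75252 CPM (SD, n = 3). Initiator tRNA fragments totalled 1363 ± 762 and 3406 ± 1864 CPM, and those of Leu-TAG 162 ± 64.1 and 478 ± 305 CPM (SD, n = 3). The total of mt-Leu-TAA was 5148 ± 123 CPM in MCT and 7238 ± 2181 CPM in control (SD, n = 3). None of the 66 passed limma's test (lowest adjusted p = 0.969). With the ratio of mitochondrial to nuclear reads as a covariate, mt-Ser-GCT alone passed, at a log2 fold change of 1.02 ± 0.29 (SE, limma adjusted p = 0.0388), against 1.07 ± 0.80 (SE) without it. Its own reads are a large part of that ratio, 27.7% of all reads in MCT 1, where mitochondrial fragments took 51.8%, and 25.2% in MCT 3, where they took 71.3%. The fit thus adjusts for a value that contains the one tested, so this call is no evidence of a difference.

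For the 3618 fragments used, the authors' deposited table gave 82 fragments with an unadjusted p under 0.05, of which 45 were higher and 37 lower in MCT, and a q-value of 1 for each of the 3618. Of these 82, 40 were also among the 86 of the limma test, and the direction was the same for all 40. In the authors' deposited table the 35 nt fragment of tRNA-Gly-CCC-2 had the smallest p-value of those used, 0.000915, with a log2 fold change of 3.03. For the mt-Leu-TAA fragment from position 30 to 60 the authors' deposited table gave a log2 fold change of -3.50 and a p-value of 0.00219.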

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

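The count of 0 fragments past the adjusted threshold held in all 20 settings tried, among them edgeR and DESeq2, with the lowest adjusted p of any fragment between 0.0597 (mitochondrial to nuclear ratio as a covariate) and 1. The 86 fragments at an unadjusted p under 0.05 and a fold of at least 1.5 ranged from 33 (without control 3) to 303 (without control 1) over the libraries left out. They numbered 145 when scaled within mitochondrial and nuclear fragments and 394 with the covariate. Classes ranged from 0 to 5 over the libraries left out. Lists called numbered 8, and from 3 to 7 over the libraries left out, of which 3 or 4 were among the 8 with the same direction. They numbered 10 without the lowest 25% of fragments (all 8 among them, in the same direction), 7 at a pseudocount of 0.1, 7 with the covariate, 4 after quantile normalization, 5 after median centring, 5 at a pseudocount of 5, 5 when scaled within mitochondrial and nuclear fragments, and 0 with an estimated correlation, with fry and with fry in either direction. Parent tRNAs numbered 1 with the covariate, mt-Ser-GCT, whose own reads are part of that covariate, and 0 in the other settings run. Parent tRNAs were not tested with the filter, with limma without trend or with robust fitting, or with edgeR and DESeq2. The cause of these shifts was not tested, and where a library was left out the number of samples was smaller too. The count at an unadjusted p under 0.05 rose without MCT 2 and without control 1. These libraries part from the rest of their group in the split by mitochondrial share described below. The scaling within origins, the covariate, edgeR, DESeq2, parent sums and shares were chosen after seeing the data.

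The tRNA-Gly list was called in 12 of 14 other settings of camera at the preset correlation, each time as higher, and not without MCT 2 or without control 1, and its call was lost with an estimated correlation (adjusted p = 0.781) and with fry (adjusted p = 0.969). The MCT minus control difference in the mitochondrial share ranged from -9.75 to 17.96 points over the libraries left out, that of nuclear tRNA-Gly from -16.2 to 9.89 points and that of tRF-5c from -17.3 to 9.88 points. For the 36 named fragments, 0 of 638 values under 18 settings passed the threshold. Of these values 501, under 14 settings, differed from the reported ones and 0 reversed direction, which says little since the fragments were picked for a low p. Their size moved, for mt-Leu-TAA 30 to 60 from -4.00 to -5.19 and -2.95 with pseudocounts of 0.1 and 5. For Gln-CTG 13 to 41 it moved from 3.43 to 4.57 and 2.55 with the same pseudocounts.

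With the replicate number as a block, 0 fragments passed, 105 had an unadjusted p under 0.05 and 3 lists were called. Deviations of same-numbered libraries correlated at 0.14, 0.46 and -0.34 across fragments. MCT 1 and MCT 2 correlated best with the control of their number, and MCT 3 with control 1 (0.54). The labels do not say that the numbers pair animals, and these correlations do not decide it. Log2 of raw values was not run, since the table gives none beside CPM, nor was a mean per RNA name, since no name repeats. Depth limits low fragments most, since 1 read is worth up to 4.52 CPM.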

Other observations

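The tests of the 3 patterns below and the comparisons with other splits of the libraries were chosen after the results were seen, while the counts of fragments, classes and lists in the real split were planned. The patterns are hypotheses found and tested on the same libraries. Longer 5′ fragments of the sister gene tRNA-Gly-CCC-1, outside the rule for named fragments and chosen after their values were seen, lay on the same side as those of tRNA-Gly-CCC-2. The 34, 35 and 36 nt forms stood at 536 ± 359, 793 ± 331 and 312 ± 79.8 CPM in MCT against 120 ± 21.4, 248 ± 84.0 and 84.6 ± 41.5 CPM in control (SD, n = 3). The 35 nt forms of tRNA-Gly-GCC-1, at 25996 ± 10210 against 28932 ± 4675 CPM, and of tRNA-Gly-CCC-4, at 741 ± 253 against 742 ± 149 CPM, did not show that difference (SD, n = 3). For mt-Leu-TAA, the abundant 40 nt fragment from position 30 to 69 stood at 414 ± 450 CPM in MCT and 818 ± 466 CPM in control (SD, n = 3), with overlap between the groups.

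Fragments of Gly-CCC-1 and Gly-CCC-2 of 34 to 36 nt stood higher in MCT. A difference in library composition is argued against as the whole cause by their log2 ratios to Gly-GCC-1 forms with the same ends, taken within each library. These ratios differed by 1.96 and 2.74 (MCT minus control, groups apart), against 1.43 and 1.54 at most in the 9 other splits of the libraries. Where the groups lie apart, the real split of 6 libraries must give the largest difference, so the other splits add nothing. Without MCT 2 the ratios differed by 1.33 and 2.29, against 1.17 and 1.65 in other splits of the 5. The groups stayed apart with any library left out, though for Gly-CCC-1 other splits reached 1.94 and 1.93 against 1.89 and 1.87 without control 2 and control 3, and the exact permutation p of 0.1 for each ratio is the smallest this design gives (adjusted 0.125 over 5 ratios). A general lengthening of 5′ fragments is not decided by the ratios to Gly-GCC-1, though they were taken at equal lengths. Lengthening would leave these ratios flat only if both tRNAs had the same spread of lengths, which is unknown here. For Gly-CCC-2, the log2 ratio of 34 to 36 nt over 30 to 32 nt forms less that of other nuclear tRNAs in the same library was also taken. It stood at 0.84 ± 0.69 in MCT and -2.36 ± 0.29 in control (SD, n = 3), a difference of 3.20 against 1.71 at most in other splits. Those other tRNAs include the long forms of Gly-GCC-1 but not its short forms, which are shared with Gly-CCC-1 and named for it. The value is thus no length ratio against the same tRNAs and cannot decide on a general lengthening. Base errors in Gly-GCC-1 reads would be G33C for Gly-CCC-1 and also G15A for Gly-CCC-2 (from the 5′ end). Gly-CCC-2 relative to Gly-CCC-1 was at least 2.36 times as frequent as Gly-CCC-1 relative to Gly-GCC-1 in all 6 libraries. That quotient takes G33C and G15A to be equally frequent. At 31 nt, Gly-CCC-2 stood at 278 ± 225 CPM in MCT and 249 ± 154 CPM in control (SD, n = 3), beside 169880 and 165123 CPM without G15A. At 34 to 36 nt it stood at 0.15 times Gly-CCC-1 or more in each library. This argues against errors as its whole source. The ratio of Gly-CCC-1 to Gly-GCC-1 was at least 8.43 times higher at 34 than at 35 nt. Loss of G33 turns a 35 nt Gly-GCC-1 read into the 34 nt Gly-CCC-1 form, so errors stay open for Gly-CCC-1. MCT treatment, a general lengthening of 5′ fragments, a difference between the animals and the choice of these fragments out of 3618 for their low p stay open.

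The ends of the mt-Leu-TAA fragments compared here were picked after their values were seen, and not every end between 58 and 63 was included. Fragments of mt-Leu-TAA from position 30 to 58, 59, 60 or 63 stood lower in MCT. Library composition is argued against as the whole cause by their log2 ratio to fragments from position 30 to 67 through 69, taken within each library. That ratio differed by -2.57 (MCT minus control, groups apart, exact permutation p = 0.1), against 1.86 at most in other splits. Exceeding 1.86 follows from the groups being apart and adds nothing to that p. Without MCT 1 the difference was -3.18, against 2.37 at most in other splits. With control 1, 2 or 3 left out, other splits reached 2.82, 2.81 and 2.53 against -2.72, -2.70 and -2.29, with the groups apart each time. A loss of shorter mitochondrial fragments throughout is argued against as the whole cause, since that ratio less the log2 ratio of 29 to 34 nt over 38 to 40 nt fragments of other mitochondrial tRNAs in the same library was -3.29 ± 1.499 in MCT and -0.88 ± 0.67 in control (SD, n = 3). The difference was -2.41, against 1.91 at most in other splits, which again follows from the groups being apart, and -1.55 without MCT 2. Without control 1 another split of the remaining libraries gave a larger difference than the real split. Treatment and the choice of these fragments for their low p stay open, and the counts are small.

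The libraries split across the groups by their mitochondrial share. Among the 10 splits of the 6 libraries into 3 and 3, MCT 1, MCT 3 and control 1 against the rest gave 526 fragments past the adjusted limma threshold and each of the other 9 gave 0, which points to a structure of the samples that does not follow the treatment labels. The libraries of that side are also the deepest, with 312739, 507542 and 538909 reads in MCT 1, MCT 3 and control 1. MCT 2, control 2 and control 3 had 258452, 193423 and 290322 reads. Depth of counting is argued against as the whole cause, since 220 fragments passed after thinning to 193423 reads per library. Thinning evens out counting only, so a difference between samples or libraries that goes with depth stays open. A few abundant fragments are argued against as the whole cause, since 419 passed without the 20 most abundant. A difference in the lengths selected on the gel is argued against as the whole cause, since 764 passed with each length scaled to the same total in every library; at one common length distribution the mitochondrial share still ranged over 18.4 points, against 58.1 as deposited, so lengths go with a part of it. A swap of the labels of MCT 2 and control 1, or an unrecorded batch, would give the same split and stays open, since no fragment here marks the treatment.

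The 10 splits are too few for a share under 0.05. For fragments past the adjusted threshold the real split gave 0 and the highest other split 526, and all 10 gave as many. For fragments at an unadjusted p under 0.05 the values were 86 and 1166, with 5 splits giving as many. Classes numbered 0 in the real split and 8 in the highest other (10 splits gave as many), lists 8 and 10 (5 splits), and parent tRNAs 0 and 46 (10 splits).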
